A study of Mus musculus with 24 samples.

How the data were processed

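Total RNA of P19 cells, a mouse embryonal carcinoma line that behaves as a pluripotent cell in culture, was measured on Affymetrix expression arrays. The 12 RNA samples form 4 groups of 3: monolayer and suspension cultures, each at a stage labelled D1 and at a stage labelled D2. The labels do not spell out D, and they name no inducer. Each RNA was hybridised to 2 chips, MOE430A and MOE430B, which gives 24 arrays. Groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates of a group are separate cultures, so the spread between samples behind every p-value may be technical.

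The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, which give no version of it. The deposited intensities had been scaled by the authors: the 2% trimmed mean lay at 1500 or 1501 on every array, so the deposited scaling was kept. There were 22690 probe sets on MOE430A and 22575 on MOE430B. The MAS5 detection calls were not used here, so a low signal could not be marked as absent. Arrays have no read depth, and their number limits the precision.

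Signals were turned into log2 values after adding an offset, the 10th percentile of all signals of the chip, which was 51.0 on MOE430A and 108.1 on MOE430B. Folds of low genes are understated on this scale. A probe set was tested if at least 3 of its 12 arrays exceeded the chip's median signal, 599.8 on MOE430A and 846.4 on MOE430B. Control probe sets were left out. Of 164 probe sets present on both chips, the 100 that were not controls were counted once, from MOE430A. This left 12689 and 13827 tested probe sets, 26516 in all. Of the 100 non-control probe sets on both chips, the differences measured by the 2 chips correlated across probe sets with Pearson's r between 0.458 and 0.807 over the 4 pairwise comparisons; probe sets are not independent replicates.

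Each comparison was tested with limma 3.58.1 in R 4.3.3. The model had 1 mean per group and pooled the spread over all 12 arrays of a chip, with a moderated variance that followed signal level. P-values were two-sided and adjusted by Benjamini-Hochberg over the probe sets of both chips together, and a probe set passed at an adjusted p under 0.05. The 5 comparisons were suspension against monolayer at D1, the same at D2, D2 against D1 in monolayer, D2 against D1 in suspension, and the interaction of culture and stage, which is the difference between the last 2. The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined.

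Gene symbols came from the platform annotation, and updating them through Entrez gene IDs changed 0 symbols. Over both chips 35067 probe sets had 1 symbol, 936 had several and 9262 had none in this annotation. No gene was named from a probe set with several symbols or none. Each gene was represented by its tested probe set with the highest mean, which gave 12727 genes. The naming rule took, for each comparison of culture, up to 10 genes with the largest rise and up to 10 with the largest fall, and for the other comparisons up to 5 of each. These had to pass the test, have groups that did not overlap, which 3 against 3 gives by chance in 10% of cases, and have a higher group mean above the chip's 75th percentile of signals, 1719 on MOE430A and 1973 on MOE430B. Up to 4 members of each list with the lowest adjusted p were added, and Pou5f1, Nanog, Sox2, Cdh1 and Actb were named in every comparison. Gapdh was fixed too, but it had no tested probe set with a single symbol. One more gene fixed in advance is not reported here.

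Of 30 gene lists fixed in advance, 29 had at least 5 represented genes and were tested, and the germ cell list was not. Some lists were measured only in part, such as 15 of 27 primitive streak genes, 8 of 19 trophoblast markers and 7 of 19 blood cell markers. The lists were naive pluripotency, primed epiblast, primitive streak, mesoderm and muscle, primitive and visceral endoderm, neural, retinoic acid response, Wnt targets, Nodal and TGF-beta targets, BMP targets, Notch, FGF and ERK feedback, immediate early genes, hypoxia, cholesterol biosynthesis, ATF4 and ER stress, heat shock, p53 targets, S phase, G2 and mitosis, epithelial adhesion, mesenchymal transition, SRF and YAP targets with the actin cytoskeleton, integrins and matrix, fibroblast, trophoblast and blood cell markers, apoptosis and imprinted genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison. Camera compares the members of a list with all other genes and, at this preset, treats genes as nearly independent. Its p-values can therefore be very small with 3 samples per group, and they do not measure agreement between samples. Calls were repeated with an estimated correlation and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. Some lists share genes with the primitive streak list, such as Fst (Nodal), Sp5 (Wnt), Fgf8 (FGF), and Cdx2 and Eomes (trophoblast). Calls of these lists are not independent of each other.

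The scanner experiment files, per the file headers, place the arrays in 3 wash batches: an earlier run on each of 2 fluidics stations, and a later run that holds replicate 3 of every group. Each batch holds 1 array of every group on each chip, so a batch term leaves the estimated differences as they are and changes only their spread. Values within batches are printed in the order station 1, station 2, later run. At D1 the samples of one replicate number share a wash batch. Replicate numbers come from the labels. Deviations from the group means correlated between same-numbered monolayer and suspension samples at D1 with r = 0.114, 0.214 and 0.172 across probe sets, each above 0.1, so the numbers were taken to pair the samples there; in the other comparisons at least 1 pair lay lower. Sample codes in the file headers are shared by same-numbered monolayer and suspension samples at D1 and at D2, but their meaning is not stated.

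The procedure was tested on simulated data drawn from the real means and spreads, with 200 probe sets changed in suspension at D1. The noise was drawn independently for each probe set and array, without the pairing or wash batches of the real arrays. Recovery and false calls under such shared variation were not simulated. After the filter 64 probe sets of each fold were tested: 3.12% were recovered at 1.5-fold, 20.3% at 2-fold and 71.9% at 4-fold, among 26408 tested, with 1 false call. Alternatives covered the scaling, offset, filter, variance model, array weights, replicate and wash batch blocks, adjustment, threshold, samples in the fit and leaving out each RNA sample.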

Results

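The series measured how growth as aggregates in suspension, in place of growth as an attached monolayer, changes the transcripts of P19 mouse embryonal carcinoma cells. Monolayer and suspension cultures were each sampled at D1 and D2, with 3 RNA samples per group, and every RNA was read on 2 chips. Median signals per array ran from 510.6 to 636.7 on MOE430A and from 758.9 to 923.4 on MOE430B. The replicate 3 arrays, all from the later wash run, had median correlations with the other arrays of 0.938 to 0.945 on MOE430A and 0.832 to 0.855 on MOE430B, against 0.945 to 0.954 and 0.862 to 0.881 for the earlier arrays.

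At D1, suspension cells held less mRNA of the YAP targets Ccn1 and Ccn2 and more of Galnt6 and Fst. Ccn2, a secreted matrix-associated protein and YAP target, fell from a signal of 4438 ± 430 to 1408 ± 184 (SD, n = 3), a log2 difference of -1.62 ± 0.20 (SE). Amotl2, a regulator of YAP, fell by 1.23 and Col18a1, a basement membrane collagen, by 1.20 on the log2 scale. Gdf3, a TGF-beta family ligand of pluripotent cells, fell from 13810 ± 2184 to 5856 ± 782 (SD, n = 3). Galnt6, a glycosyltransferase, rose 5.31-fold, from 496.4 ± 135 to 3055 ± 211 (SD, n = 3). At D2 it read 1259 in monolayer and 1727 in suspension, a log2 difference of 0.44 that did not pass. The D1 monolayer signal of Galnt6 lay below the median signal of MOE430B, 846.4, and was not tested against background. The size of its rise is therefore uncertain. Fst, which encodes the activin antagonist follistatin, rose 4.80-fold, from 10520 ± 5831 to 44930 ± 3308 (SD, n = 3). The receptor gene Epha1 rose 3.28-fold, the connexin gene Gjc1 3.25-fold and the planar polarity gene Prickle1 2.50-fold, each by 1 called probe set. The lowest log2 difference was 0.13 among the 3 tested probe sets of Epha1 and 0.80 among the 2 of Gjc1. For Prickle1, 1 of the 3 tested probe sets pointed the other way.

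With limma, 14 of 26516 probe sets passed at D1, 7 higher and 7 lower in suspension, with adjusted p between 0.0127 and 0.0439. An unadjusted p under 0.05 was found for 1376, where 1326 are expected by chance. With the replicate number as a block the count was 30, 19 higher and 11 lower, and with the wash batch as a block it was 15. These 2 blocks differ only in where replicates 1 and 2 of suspension at D2 fall, so the blocked count at D1 depends on that. Within the 3 wash batches Ccn2 differed by -1.38, -1.76 and -1.74 and Fst by 3.40, 2.02 and 1.36. The count was 0 without monolayer replicate 2, suspension replicate 1 or suspension replicate 2, 2 without monolayer replicate 3 and 4 without monolayer replicate 1. Without suspension replicate 3 it was 13, but 1 higher and 12 lower, and only 6 of them were among the 14. Leaving out D2 samples, which lend only their spread, gave 8, 5 and 5 without monolayer replicates 1, 2 and 3 and 4, 6 and 6 without suspension replicates 1, 2 and 3. The count was 4 (1 higher) after quantile normalization, 8 (5 higher) after median centring and 0 without the later wash run.

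Among the gene lists at D1, the SRF and YAP list fell: of 38 measured members 3 fell, 0 rose and 35 did not pass, and 8 fell and 1 rose adjusted over the list alone. Its median was -0.28 (camera in limma, adjusted p = 1.23e-08; adjusted p = 0.0217 with an estimated correlation), and -0.42, -0.25 and -0.20 in the 3 wash batches. Ccn1, a matricellular YAP target, fell by 1.51 on the log2 scale, and Ajuba differed by -1.37 ± 0.23 (adjusted p = 0.0536, and 0.000952 with the replicate block). The primitive streak list, genes of the embryonic region where mesoderm and endoderm form, rose with a median of 0.93 (adjusted p = 1.89e-09; adjusted p = 0.076 with an estimated correlation). Fst was the 1 of its 15 measured members that rose and 0 fell, against 7 that rose adjusted over the list alone. Foxa2, an endoderm transcription factor, differed by 1.48 ± 0.27, Amot by 1.44 ± 0.28 and the Wnt target Sp5 by 2.07 ± 0.48, none past the test over all genes without a block. With the replicate block, which also ties the D2 samples by number, Foxa2 (adjusted p = 0.0267) and Amot (0.00695) passed and Sp5 (0.238) did not. The within-batch medians of the list were 1.19, 0.72 and 0.65, and its median was 0.56 without monolayer replicate 2 (adjusted p = 6.93e-06). Sp5 read only 57.7 to 133 in monolayer, not tested against background, so the size of its difference is uncertain. Over the same arrays the 18S ribosomal control signal on MOE430A was 28890 ± 17080 in monolayer and 56080 ± 12670 in suspension (SD, n = 3; two-sided exact permutation p = 0.2). That signal was higher in suspension in each of the 3 same-numbered pairs on both chips (2.2-fold on MOE430A and 2.1-fold on MOE430B). The 3' to 5' ratio of the beta-actin control on MOE430B was 1.04 ± 0.08 in monolayer and 1.29 ± 0.04 in suspension (SD, n = 3; exact permutation p = 0.1, the smallest that 3 against 3 can give).

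The other lists called at D1 were called by camera at the preset correlation alone. This also held for the primitive streak list (adjusted p = 0.058 with fry). Wnt targets rose (median 0.28, adjusted p = 0.00338; adjusted p = 0.309 with an estimated correlation), with Lef1 at 1.34 ± 0.26 (adjusted p = 0.111, and 0.0443 with the replicate block) and 0 of 17 members past the test, 2 adjusted over the list alone. Nodal and TGF-beta targets rose (median 0.21, adjusted p = 0.00338; adjusted p = 0.076 with an estimated correlation), with Fst the 1 of 11 members that passed in both adjustments. FGF and ERK feedback genes rose (median 0.23, adjusted p = 0.0183; adjusted p = 0.416 with an estimated correlation), with Spry2 at 1.03 ± 0.21 (adjusted p = 0.236, and 0.0267 with the replicate block) and Fgf8 at 1.16 ± 0.27; 0 of 17 passed, 4 adjusted over the list alone. Cholesterol biosynthesis rose (median 0.13, adjusted p = 0.0234; adjusted p = 0.604 with an estimated correlation), with 0 of 21 members past either adjustment. Blood cell markers fell (median -0.52, adjusted p = 0.0108; adjusted p = 0.172 with an estimated correlation), with Runx1 at -1.04 ± 0.25; 0 of 7 passed, 1 adjusted over the list alone. The within-batch medians in the order above were 0.55, 0.09 and 0.23 for Wnt, 0.27, 0.42 and 0.24 for Nodal, 0.17, 0.07 and 0.12 for FGF, 0.12, 0.19 and 0.15 for cholesterol, and -0.52, -0.56 and -0.17 for blood cells. Each of these 5 calls ended on leaving out some single samples: Wnt without monolayer replicate 2 (adjusted p = 0.157), Nodal without suspension replicate 2 (0.0946), and FGF without monolayer replicate 3 (0.141), suspension replicate 1 (0.0664) or suspension replicate 2 (0.123, with a median of -0.01). Cholesterol ended without monolayer replicate 1 (0.0776), monolayer replicate 2 (0.0726), suspension replicate 2 (0.0946) or suspension replicate 3 (0.0677), and blood cells without monolayer replicate 1 (0.0776) or suspension replicate 2 (0.0946). Other medians moved with the call held: without monolayer replicate 1 to 0.47 for Wnt and 0.14 for FGF, without monolayer replicate 2 to 0.36 for Nodal. Without the later wash run the cholesterol call ended (adjusted p = 0.0759), and the medians were 0.05 for FGF and 0.35 for Nodal.

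Of the 22 lists not called at D1, the fibroblast markers came nearest (median -0.27, adjusted p = 0.0718). All 8 of their measured members lay below 0 and 0 passed, with within-batch medians of -0.66, -0.53 and 0.10. The other 21 had adjusted p between 0.121 for G2 and mitosis and 0.981 for primed epiblast. The median of the BMP, ATF4, epithelial and apoptosis lists lay below 0 at D1 while the test pointed up. The core pluripotency genes did not pass at D1: Pou5f1 differed by 0.10 ± 0.15, Nanog by -0.12 ± 0.18 and Sox2 by 0.20 ± 0.16, and neither did Cdh1 (-0.16 ± 0.27) or Actb (0.06 ± 0.15).

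**Figure D1:**
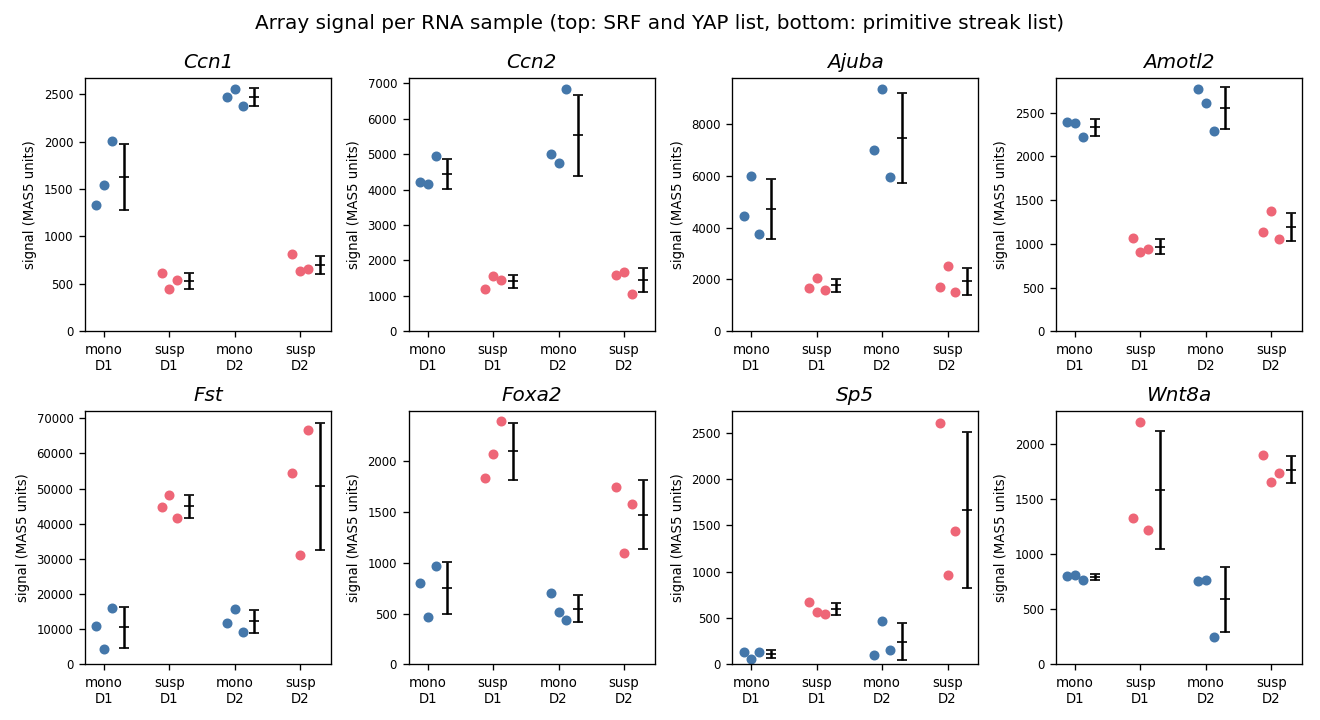
Array signal in MAS5 units (vertical axes, linear, from 0) of 4 genes of the SRF and YAP list and 4 of the primitive streak list in monolayer (mono) and suspension (susp) samples at D1 and D2. Points are the 3 RNA samples of a group and bars the mean ± SD; Ccn2 averaged 4438 and 1408 at D1 and 5528 and 1439 at D2.

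At D2, Ccn1, Ccn2, Col18a1, Amotl2 and Gdf3, which had passed at D1, were again lower in suspension, and Ajuba, Cald1 and Irak1bp1 passed as well. Ccn2 fell from 5528 ± 1145 to 1439 ± 341 (SD, n = 3), a log2 difference of -1.91 ± 0.20 (SE). Ajuba, a LIM protein that acts on YAP, fell 3.80-fold, Col18a1 3.54-fold, Ccn1 3.35-fold, the actin-binding protein gene Cald1 3.07-fold, Gdf3 2.69-fold, Irak1bp1 2.45-fold and Amotl2 2.10-fold. The transcript 4930542N06Rik was 4.77-fold higher in suspension at D2, at 3130 ± 803 against 568.3 ± 145 in monolayer (SD, n = 3). At D1 it read 2737 ± 570 in monolayer and 2161 ± 736 in suspension, so the difference at D2 went with a lower monolayer signal. That D2 monolayer signal lay below the median signal of MOE430B, 846.4, and was not tested against background. The size of the difference is therefore uncertain.

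With limma, 14 probe sets passed at D2, 3 higher and 11 lower in suspension, and 18 with the wash batch as a block. The count was 41 (16 higher) with array weights. Without the later wash run it was 1, a probe set not among the 14. Within the wash batches Ccn2 differed by -1.55, -1.54 and -2.65. The count was 5 without monolayer replicate 3, 7 without monolayer replicate 1, and 9 without monolayer replicate 2, suspension replicate 1, suspension replicate 3 or the D1 suspension replicate 1. The D1 and D2 comparisons shared 5 called probe sets, all lower (Ccn1, Ccn2, Col18a1, Amotl2 and Gdf3); their differences come from separate samples, but their tests share a spread pooled over all 12. Across 12727 genes, which are not independent replicates, the 2 sets of differences correlated with Pearson's r = 0.197 and Spearman's rho = 0.182.

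The SRF and YAP list fell at D2 as at D1: of 38 members 5 fell, 0 rose and 33 did not pass, and 12 fell and 1 rose adjusted over the list alone (median -0.28, camera adjusted p = 2.95e-12; adjusted p = 0.00659 with an estimated correlation). Its within-batch medians were -0.27, -0.14 and -0.38, and its median was -0.18 without the later wash run (adjusted p = 1.48e-08). The primitive streak list rose (median 0.82, camera adjusted p = 7.68e-11, and adjusted p = 0.0896 with an estimated correlation). All 15 of its measured members, of 27 listed, lay above 0, 0 passed and 7 rose adjusted over the list alone. Sp5 differed by 2.64 ± 0.48 (monolayer signals 106 to 473, not tested against background), Fst by 2.00 ± 0.37 and Wnt8a, a Wnt ligand of the streak, by 1.63 ± 0.33, and the within-batch medians were 1.12, 0.60 and 1.02. The ATF4 and ER stress list, genes induced by amino acid shortage and by unfolded protein, fell (median -0.45, adjusted p = 1.29e-14; adjusted p = 0.234 with an estimated correlation). Of its 43 members 42 lay below 0, 0 passed and 8 fell adjusted over the list alone, with the chaperone gene Hsp90b1 at -0.61 ± 0.14 and Manf at -0.94 ± 0.22; the within-batch medians were -0.78, -0.23 and -0.37.

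Further lists were called at D2 by camera at the preset correlation alone, as was the ATF4 and ER stress list (adjusted p = 0.126 with fry). G2 and mitosis rose (median 0.22, adjusted p = 0.000108; adjusted p = 0.318 with an estimated correlation), as did cholesterol biosynthesis (0.29, adjusted p = 0.00082; adjusted p = 0.402 with an estimated correlation). FGF and ERK feedback (0.16, adjusted p = 0.0143; adjusted p = 0.389 with an estimated correlation) and trophoblast markers (0.44, adjusted p = 0.0212; adjusted p = 0.388 with an estimated correlation) rose, and Wnt targets rose (0.31, adjusted p = 0.0464; adjusted p = 0.402 with an estimated correlation). No member of these 5 lists passed over all genes, and adjusted over the list alone 2 Wnt targets did. Of the 8 measured trophoblast genes, Cdx2 and Eomes also belong to the primitive streak list. The within-batch medians were 0.30, 0.09 and 0.19 for mitosis, 0.08, 0.18 and 0.48 for cholesterol, 0.16, 0.17 and 0.30 for FGF, 0.03, 0.41 and 0.98 for trophoblast and 0.27, 0.18 and 0.77 for Wnt. Without monolayer replicate 3 the trophoblast (adjusted p = 0.308), FGF (0.392) and Wnt (0.545) calls ended. The FGF call also ended without suspension replicate 1 (0.0762), trophoblast without suspension replicate 2 (0.0516) and cholesterol without monolayer replicate 1 (0.0597). The Wnt call also ended without suspension replicates 1 (0.0762), 2 (0.072) or 3 (0.0821) or the D1 suspension replicates 2 (0.0535) or 3 (0.058), and with the wash batch as a block (0.0634). Other medians moved with the call held: mitosis to 0.13 without suspension replicate 1 (adjusted p = 0.0198), trophoblast to 0.69 without monolayer replicate 2, and FGF to 0.24 and 0.37 without monolayer replicates 1 and 2 and to 0.37 without suspension replicate 3. Without the later wash run the cholesterol (0.124), FGF (0.12), trophoblast (0.332) and Wnt (0.814) calls ended.

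The remaining lists did not pass at D2. Adjusted p was 0.519 for naive pluripotency, 0.974 for primed epiblast, 0.698 for mesoderm and muscle, 0.0695 for primitive and visceral endoderm, 0.826 for neural genes, 0.433 for retinoic acid response, 0.339 for Nodal, 0.161 for BMP and 0.826 for Notch. It was 0.0598 for immediate early genes, 0.0695 for hypoxia, 0.0598 for heat shock, 0.92 for p53 targets, 0.705 for S phase, 0.826 for epithelial adhesion, 0.698 for mesenchymal transition and 0.272 for integrins and matrix. It was 0.649 for fibroblast, 0.592 for blood cell markers, 0.974 for apoptosis and 0.698 for imprinted genes. The median and mean of the primed epiblast, blood cell and apoptosis lists differed in sign or from the direction of the test. Pou5f1 differed by -0.10 ± 0.15, Nanog by 0.54 ± 0.18, Sox2 by -0.29 ± 0.16, Cdh1 by -0.53 ± 0.27 and Actb by -0.12 ± 0.15, none past the test.

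**Figure D2:**
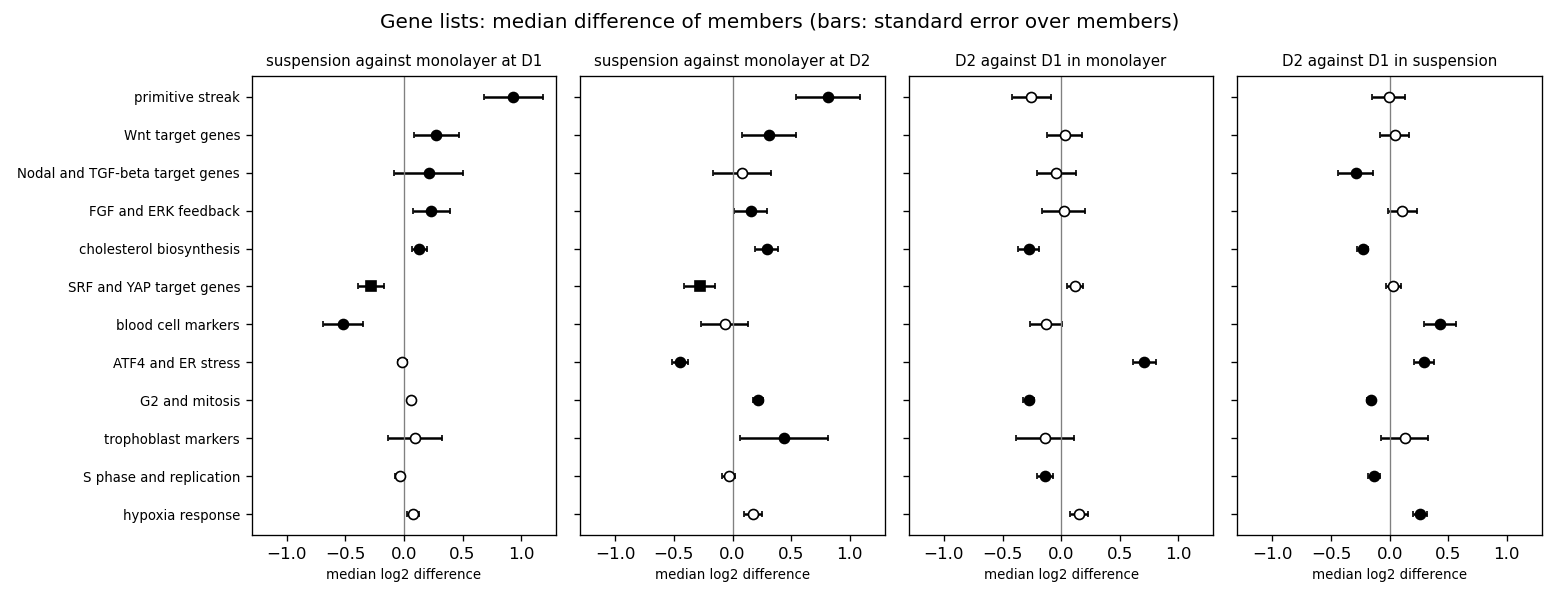
Median log2 difference of list members (horizontal axis) in the 4 pairwise comparisons, with bars of 1 standard error over members. Filled symbols passed camera at adjusted p under 0.05 and squares also passed with an estimated correlation, which held for the SRF and YAP list at D1 and D2.

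From D1 to D2 in monolayer, genes of the stress response to amino acid shortage and unfolded protein rose as a list. The ATF4 and ER stress list had a median of 0.71 (camera adjusted p = 5.13e-30; adjusted p = 0.117 with an estimated correlation), and 41 of 43 members lay above 0. None of them passed over all genes, and 30 rose adjusted over the list alone. The transcription factor gene Cebpb went from 667.7 to 3128 (log2 difference 2.20 ± 0.38, SE), Cth, a cysteine synthesis enzyme, differed by 0.89 ± 0.16, Sesn2 by 1.14 ± 0.21 and the serine synthesis gene Psph by 0.93 ± 0.18. Within the wash batches the list medians were 0.61, 0.77 and 0.80. Over the same arrays the 18S ribosomal control signal was 1.78-fold higher at D2 on MOE430A and 1.64-fold on MOE430B, higher in each of the 3 same-numbered samples (two-sided exact permutation p = 0.3 and 0.4). The B1 repeat control was 2.44-fold and 2.37-fold lower, with no overlap (exact permutation p = 0.1 on each chip, the smallest that 3 against 3 can give).

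The proliferation and sterol lists fell from D1 to D2 in monolayer. G2 and mitosis had a median of -0.28 (adjusted p = 1.99e-08; adjusted p = 0.15 with an estimated correlation), with Plk1, a mitotic kinase, at -0.63 ± 0.16, and 2 of 41 members fell adjusted over the list alone. S phase had a median of -0.14 (adjusted p = 0.0032; adjusted p = 0.211 with an estimated correlation), with Ccne1, which encodes cyclin E1, at -1.20 ± 0.34 and 3 of 39 adjusted over the list alone. Cholesterol biosynthesis had a median of -0.28 (adjusted p = 7.59e-05; adjusted p = 0.488 with an estimated correlation), with Nsdhl at -0.82 ± 0.20 and 2 of 21 adjusted over the list alone. Within-batch medians were -0.12, -0.32 and -0.35 for mitosis, -0.23, -0.13 and -0.14 for S phase and 0.02, -0.36 and -0.57 for cholesterol, and without the D2 monolayer replicate 2 the S phase call ended (adjusted p = 0.0587) and the cholesterol median was -0.47 (adjusted p = 1.84e-10). Nanog differed by -0.90 ± 0.18, with an adjusted p of 0.178, Pou5f1 by 0.32 ± 0.15, Sox2 by 0.26 ± 0.16, Cdh1 by 0.47 ± 0.27 and Actb by 0.06 ± 0.15.

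With limma, 2 probe sets passed in this comparison, both named after their values were seen because the rule for bright genes left them out. Plekhg5 rose from 337.1 ± 56.0 to 1194 ± 172 and Cbr3, a carbonyl reductase, fell from 949.6 ± 353 to 104.2 ± 29.7 (SD, n = 3), both with an adjusted p of 0.0468. Within the wash batches Plekhg5 differed by 1.73, 1.60 and 1.72 and Cbr3 by -2.19, -3.19 and -2.52. The Plekhg5 signal of 337.1 at D1 and the Cbr3 signal of 104.2 at D2 were low and not tested against background. The sizes of both differences are therefore uncertain. With the wash batch as a block 0 passed, with array weights 33 and without the later wash run 1, which was neither of these probe sets. Leaving out single samples gave 0 to 225 calls. There were 225 without the D1 monolayer replicate 2, 4 without the D1 suspension replicate 2 and 0 without any other.

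From D1 to D2 in suspension, 0 probe sets passed with limma, also with the wash batch as a block, and 1555 had an unadjusted p under 0.05, where 1326 are expected by chance. Lists were called by camera and by no other set test. The ATF4 and ER stress list rose (median 0.30, adjusted p = 3.35e-05; adjusted p = 0.603 with an estimated correlation), with Cth at 0.70 ± 0.16 and Atf3 at 1.97 ± 0.46, and 2 of 43 members adjusted over the list alone. S phase fell (-0.14, adjusted p = 0.000212; adjusted p = 0.255 with an estimated correlation), G2 and mitosis fell (-0.16, adjusted p = 0.000212; adjusted p = 0.347 with an estimated correlation) and cholesterol biosynthesis fell (-0.23, adjusted p = 0.00186; adjusted p = 0.603 with an estimated correlation). Nodal targets fell (-0.29, adjusted p = 0.044; adjusted p = 0.306 with an estimated correlation), and blood cell markers (0.43, adjusted p = 0.0215; adjusted p = 0.306 with an estimated correlation) and hypoxia genes (0.26, adjusted p = 0.0288; adjusted p = 0.871 with an estimated correlation) rose.

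None of these lists but ATF4 had a member past either adjustment. Within-batch medians were -0.11, 0.56 and 0.35 for ATF4, -0.14, -0.19 and -0.09 for S phase, -0.02, -0.29 and -0.13 for mitosis, and -0.04, -0.41 and -0.17 for cholesterol. They were -0.34, -0.48 and -0.01 for Nodal, 0.72, 0.52 and 0.36 for blood cells and -0.48, 0.67 and 0.61 for hypoxia. The ATF4 and hypoxia shifts thus changed sign in 1 batch, which set D2 replicate 1 against D1 replicate 2. Between same-numbered samples the mean of the ATF4 list rose in each pair, from -0.39 to -0.26, -0.13 to 0.35 and -0.41 to 0.06. That of the hypoxia list fell in replicate 2, from 0.62 to 0.33, and rose in the others. Without the D2 suspension replicate 2 the ATF4 (adjusted p = 0.146), mitosis (0.146), cholesterol (0.225), hypoxia (0.217) and Nodal (0.397) calls ended. The hypoxia call also ended without the D1 suspension replicates 1 (0.757) or 3 (0.88) or the later wash run (0.753); without the D1 suspension replicate 2 its median was 0.64 and that of cholesterol -0.15, both still called. The Nodal call also ended without the D1 suspension replicate 2 (0.403) or the D2 monolayer replicates 2 (0.0542) or 3 (0.0523). Blood cells ended without the D1 suspension replicate 2 (0.288) or the D2 suspension replicates 1 (0.0564) or 3 (0.0797). The count of probe sets was 2 without the D2 suspension replicate 3. The 3' to 5' ratio of the beta-actin control on MOE430B was 1.29 ± 0.04 at D1 and 1.07 ± 0.04 at D2 in suspension (SD, n = 3; exact permutation p = 0.1). The fixed genes differed by 0.12 ± 0.15 (Pou5f1), -0.24 ± 0.18 (Nanog), -0.23 ± 0.16 (Sox2), 0.10 ± 0.27 (Cdh1) and -0.12 ± 0.15 (Actb).

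The effect of culture was not shown to differ between the stages for any single probe set: 0 passed the interaction with limma. An unadjusted p under 0.05 was found for 966, where 1326 are expected by chance. The ATF4 and ER stress list differed by a median of -0.42 (adjusted p = 3.66e-12; adjusted p = 0.514 with an estimated correlation), -0.56, -0.28 and -0.35 in the wash batches. Blood cell markers differed by 0.51 (adjusted p = 0.0172; adjusted p = 0.514 with an estimated correlation), 0.43, 0.76 and 0.32 in the wash batches, a call that ended without the D1 monolayer replicate 1 (adjusted p = 0.0823), the D1 suspension replicate 2 (0.129), the D2 monolayer replicate 1 (0.0558) or the D2 suspension replicate 3 (0.0792). No member of either list passed over all genes or adjusted over the list alone. The interaction was -0.20 ± 0.22 for Pou5f1, 0.66 ± 0.26 for Nanog, -0.49 ± 0.23 for Sox2, -0.37 ± 0.38 for Cdh1 and -0.18 ± 0.21 for Actb.

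**Figure D3:**
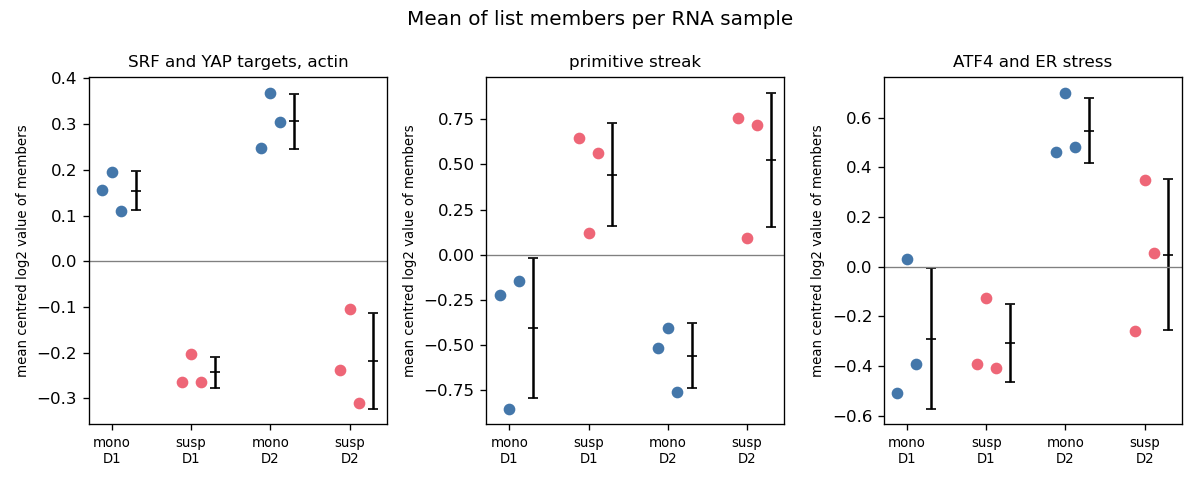
Mean centred log2 value of the members of 3 lists (vertical axes, 0 is the mean of all 12 samples) in each RNA sample; points are the 3 samples of a group and bars the mean ± SD. The ATF4 and ER stress list averaged 0.55 in monolayer at D2 and 0.05 in suspension at D2.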

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

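The 3 patterns weighed below were picked from the list results. Of the tests, the regroupings for the mean of both culture differences and, for lists, median centring, the use of wash batches and the fibroblast list were chosen only after the result was seen. The effect of culture on the ATF4 and ER stress list differed between D1 and D2 by a median of -0.42, and that on the blood cell markers by 0.51, each by a camera test of the interaction; both calls ended with an estimated correlation (adjusted p = 0.514 for each) and with fry (0.593 and 0.264). Groups hold 3 samples, too few to test single samples as outliers.

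The ATF4 and ER stress list was higher in monolayer at D2 than at D1. The shift nearest to 0 in units of its standard error was 0.72 on leaving out 1 RNA sample, 0.72 under quantile normalization or median centring, and 0.77 within a wash batch (the lowest batch median was 0.61), each more than 1 standard error over members from 0. These values argue against a single sample or the scaling as the whole source. Each wash batch holds every group, so a plain difference between batches could not make the shift whatever the values. The batch values show only that its sign held in each batch. The standard error takes the members as independent, which genes of 1 list need not be. With an estimated correlation the call ended (adjusted p = 0.117), while with fry it held (0.0237). No biological explanation beyond the stage itself was tested.

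The SRF and YAP list was lower in suspension at D2. Its shifts nearest to 0 on the same scale were -0.23 on leaving out 1 sample, -0.26 under the scalings and -0.14 within a wash batch. The last was only just beyond its standard error of 0.13. These values argue against a single sample or the scaling as the whole source. The batch values show only that the sign held in each batch. Fewer fibroblast-like cells in suspension could also lower such genes, but the check set in advance is void: 6 abundant fibroblast genes had a median change of 0.17, and only Col1a2 (0.11) and Dcn (0.56) had a tested probe set. The fixed fibroblast list had a median of 0.16 ± 0.13 (SE) over 8 genes, 0.44 ± 0.19 above the SRF and YAP list. These 8 genes did not fall with that list at D2, and their within-batch medians were -0.06, -0.04 and 0.38. But only 8 of the 20 listed genes had a tested probe set, as small a share as voids a check, so they do not decide the question. At D1 the same 8 genes were all below 0 (median -0.27). Fewer fibroblast-like cells thus stay open as a source at both stages, as does loss of attachment, which the design names.

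The primitive streak list was higher in suspension at D2. Its shifts nearest to 0 on that scale were 0.68 on leaving out 1 sample, 0.84 under the scalings and 0.60 within a wash batch. Each was more than 1 standard error from 0. These values argue against a single sample or the scaling as the whole source. The batch values show only that the sign held in each batch. The call ended with an estimated correlation (adjusted p = 0.0896) and held with fry (0.0231). Aggregation itself stays open.

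For 3 samples against 3, the 10 splits are too few for a share under 0.05. At D1 the real split gave 14 probe sets and the highest other 7, with 1 split, the real one, as large; at D2 these were 14, 0 and 1. The 3 other splits at D1 that part every same-numbered pair gave 0. In monolayer the real split gave 2 and the highest other 2, with 2 splits as large. A real count of 0 is matched by any split, so the 10 of 10 splits in suspension (highest other 1) and the 100 of 100 drawn regroupings of culture within stage for the interaction (highest other 28) say nothing about chance.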

How the results depend on the processing

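The runs without the later wash run, the wash batch block and median centring for lists, and the block with an estimated correlation were chosen after seeing the data. Against 14 probe sets at D1, the count was 4 with quantile normalization, 8 with median centring, 4 with no filter, 5 without the intensity trend, 0 without the later wash run, 0 at adjusted p under 0.01 and 1 with only the 6 arrays compared; leaving out single samples gave 0 to 13. Against 14 at D2, it was 41 with array weights, 1 without the later wash run, 5 at adjusted p under 0.01 and 6 with only the 6 arrays; leaving out single samples gave 5 to 21. Against 2 in monolayer, it was 1 with quantile normalization, 1 with the floor, 0 with the larger offset, 0 with no filter, 0 with the stricter filter, 33 with array weights, 0 with the wash batch block, 1 without the later wash run, 0 at adjusted p under 0.01 and 1 with only the 6 arrays; leaving out single samples gave 0 to 225. In suspension leaving out single samples gave 0 to 2, and the interaction gave 1 without the intensity trend and 0 otherwise. A stricter threshold can only lower a count; for the other settings the cause was not tested.

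With the replicate block the counts were 30 at D1, 89 at D2, 193 in monolayer, 0 in suspension, 0 for the interaction and 220 (against 68) for the mean culture difference of D1 and D2. Outside D1 same-numbered samples share, at D2, a header code of unstated meaning and, except for replicates 1 and 2 of suspension at D2, a wash batch. The lowest same-number correlations were 0.058 at D2, 0.073 in monolayer and 0.031 in suspension. Over all other groups, though, each of the 12 samples correlated best with one of its own number, a hint from the data and not from the design. Between the suspension groups replicate 1 did not (0.031 against 0.032). Where number and wash batch coincide, their parts in these correlations cannot be told apart. The replicate and wash batch blocks differ only in where replicates 1 and 2 of suspension at D2 fall. They gave 193 and 0 in monolayer, so that count depends on this assignment. The 14 probe sets called at D1 and the 14 at D2 were all called with the replicate block.

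The number of list calls moved, not always with the same lists: 7 at D1 became 1 with an estimated correlation, 1 with fry and 1 with the block and an estimated correlation; 8 at D2 became 1, 2 and 1, and 5 without the later wash run, 4 of them among the 8; 4 in monolayer became 0, 2 and 1; 7 in suspension became 0, 0 and 0; 2 for the interaction became 0, 0 and 0, and 1 with the median of all probe sets. Leaving out single samples gave 4 to 9, 5 to 11, 4 to 6, 2 to 7 and 1 to 4 calls. The replicate block at the preset correlation ended the Wnt call at D2 (adjusted p = 0.0957). Quantile normalization ended the calls of cholesterol at D1 (0.0663), Wnt at D2 (0.0549), Nodal (0.111) and blood cells (0.108) in suspension and blood cells in the interaction (0.0719). Without the filter the Wnt (0.116), FGF (0.116) and trophoblast (0.0969) calls at D2 ended, and without the offset Wnt at D2 (0.0596). With the median of all probe sets the blood cell calls at D1 (0.0556), in suspension (0.121) and in the interaction (0.175) and Nodal in suspension (0.292) ended. Without the later wash run the calls of cholesterol at D1 (0.0759), cholesterol (0.124), FGF (0.12), trophoblast (0.332) and Wnt (0.814) at D2 and hypoxia in suspension (0.753) ended. No called named gene changed sign in any setting run for it, but some medians of called lists did: FGF and ERK feedback at D1 (-0.01 without the D1 suspension replicate 2) and, within the wash batch of station 1, ATF4 (-0.11) and hypoxia (-0.48) in suspension and cholesterol in monolayer (0.02). Low signals limit the folds of dim genes, since the offset shrinks them.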

Other observations

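Averaged over D1 and D2, a contrast chosen after seeing the data, 68 probe sets passed, 31 higher and 37 lower in suspension. Sp5, a Wnt target, was higher in suspension (adjusted p = 0.00828, limma), but its mean monolayer signals of 107.5 at D1 and 243.4 at D2 were low and not tested against background, so no fold is given. Also higher were the endoderm transcription factor gene Foxa2 (2.65-fold), Amot (2.69-fold), Wnt8a (2.41-fold), Lef1 (2.04-fold) and the ERK feedback gene Spry2 (1.79-fold). Lower in suspension were the actin-binding genes Tpm1 (2.31-fold) and Cald1 (2.41-fold), the matrix gene Sparc (1.85-fold), Trim2 (2.14-fold) and Lpl (1.97-fold). The smooth muscle gene Tagln was lower too (adjusted p = 0.0313, limma). Its suspension signals of 421.6 at D1 and 220.3 at D2 were low and not tested against background, so its fold is not given either. These genes were picked after their values were seen. Of 100 regroupings of culture within stage, 1, the real one, gave as many, and the highest other gave 28. Of the 80 regroupings that part the same-numbered samples at D1, chosen like the contrast after seeing the data, 1 gave as many and the highest other gave 1. Of the 32 that part them at both stages, 1 gave as many and the highest other gave 0. No other regrouping that was run thus gave the count. The contrast and these sets were picked after seeing the data, and the numbers were not taken to pair samples at D2. These shares are therefore no test of chance. The count was 102 with the wash batch block, 123 with array weights, 45 with no filter, 41 without the intensity trend and 14 without the later wash run. At adjusted p under 0.01 it was 30, and with a 2-fold minimum 42. Leaving out a D1 sample, it was 45 without monolayer replicate 2, 42 without monolayer replicate 3, 36 without suspension replicate 1 and 45 without suspension replicate 3. Leaving out a D2 sample, it was 44 without monolayer replicate 2, 37 without monolayer replicate 3, 40 without suspension replicate 1 and 40 without suspension replicate 3.

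The control probe set for the B1 repeat, a short interspersed element carried in many transcripts, read 34970 ± 4511 in monolayer at D1 and 14820 ± 4712 at D2, and 31160 ± 7107 and 12250 ± 3949 in suspension (SD, n = 3, MOE430A). Every D2 array lay below every D1 array on both chips (two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 can give).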
